A study of Mus musculus with 19 samples.

How the data were processed

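The data are RNA sequencing of liver from C57BL/6 mice. Per the labels' protocols, wild-type (WT) and IL-6 knockout mice received 2 intraperitoneal injections, 3 h apart, of vehicle or of 4 mg furosemide, and livers were taken 6 h after the first injection. Furosemide is a loop diuretic, and the treated mice are labelled as having pre-renal azotemia (PRA), in which nitrogenous waste accumulates in blood because the kidneys are poorly perfused. Non-injected WT mice are labelled as the normal control. RNA was extracted with a column kit, poly(A)-selected and sequenced as read pairs on an Illumina instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which give 4 normal, 4 WT vehicle, 4 WT PRA, 4 IL-6 knockout vehicle and 3 IL-6 knockout PRA libraries.

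The authors deposited raw counts per gene, as a table of the whole series and as 1 file per library. The submitters' processing notes name HISAT2 2.2.1, SAMtools 1.13, HTSeq 0.11.3 and genome build GRCm39. The annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads from overlapping genes and from a gene and its antisense partner cannot be told apart. Genes with near-identical copies (Saa1 and Saa2, the Orm, Mup, Serpina3, C4, Cyp4a and Acot families, the globins, and Lars2, which shares sequence with mitochondrial rRNA) are uncertain to the extent that counting divided shared reads. The per-library files held the same gene counts as the series table, so a fit from them was not run. Their summary lines were kept out of library sizes and tests: reads not uniquely placed made up 14.07% to 19.15% of a library, reads outside genes 6.28% to 7.58%, and 66.95% to 71.71% were counted in genes. Of 55416 gene lines, 52083 had a symbol in the gene name table used, and these held 99.58% of all counts.

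Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on group, which left 15570 genes (15542 with a symbol), and libraries were scaled by TMM. One quasi-likelihood model with a mean per group, robust dispersion and no covariate was fitted to all 19 libraries, so that the 5 groups shared the estimate of spread. There were 7 contrasts: PRA against vehicle in each genotype, the genotype by treatment interaction (the knockout response minus the WT response), knockout against WT under PRA and under vehicle, and WT vehicle and WT PRA against normal. P-values were adjusted by Benjamini-Hochberg within each contrast, and 0.05 was the threshold. Levels are TMM-scaled CPM (each count as a share of the scaled library total) as mean ± SD over the libraries of a group, and log2 fold changes carry the standard error of the fit.

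The design, the alternatives, 42 gene lists and the rule for named genes were fixed before the data were examined. Lists were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, 2-sided, adjusted over the lists tested in a contrast, and again with a correlation estimated per list. The lists named for kidney and pancreas had 4 and 3 tested genes, under the minimum of 5, and were not tested. Members past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. Named genes had an adjusted p at or under 0.05, a mean of at least 2 CPM in the groups compared, a symbol that is not a predicted model and, between 2 groups, no overlap of CPM. From these the largest changes were taken in each direction, 12 for WT PRA against vehicle, 8 for knockout PRA against vehicle and for WT vehicle against normal, 6 for the interaction and both genotype contrasts and 4 for WT PRA against normal. A fixed set of acute phase and related genes (Il6, Saa1, Saa2, Saa3, Lcn2, Hp, Orm1, Orm2, Fgb, Serpina3n, Lrg1, Socs3, Hamp and Agt) and up to 4 members of each list past camera, by smallest p, were added. Some genes this rule names are withheld and are not reported here.

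Depth was 32073865 to 74041441 gene counts per library. A count of 0 allows up to 3 counts, which is 0.0405 to 0.0935 CPM of the library totals without TMM scaling, and such limits cover counting error only. The procedure was tested on simulated counts drawn from these libraries' means and spread, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For WT PRA against vehicle, 43.3%, 64.2% and 87.9% of them were recovered among 15292 genes, with 7 unchanged genes called. For the interaction the shares were 4.48%, 43.3% and 71.2% among 15305 genes, with 6 unchanged genes called. The lowest chi-square per degree of freedom between replicates of a group was 22.73, so no pair looked like a repeated deposit of 1 library.

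The alternatives were RLE and upper quartile scaling, no low-count filter, a filter of 1 CPM in 3 libraries, and a fold-change threshold of 1.5 (glmTreat). They also included DESeq2 1.42.0, limma-voom with sample weights, a replicate block, a fit to only the groups compared, and each library left out in turn. For lists they also included the self-contained test fry. Neighbours of Il6 were found from a GENCODE gene annotation of assembly GRCm38.p6, used only for which genes lie near each other, since it differs from the build of the counts. Other splits of the libraries, all 35 for comparisons of 2 groups and 100 drawn ones for the interaction, and tests of technical explanations are given with the additional observations.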

Results

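Poly(A) RNA was sequenced from 19 mouse liver libraries in 5 groups: 4 non-injected normal, 4 WT vehicle, 4 WT PRA, 4 IL-6 knockout vehicle and 3 IL-6 knockout PRA. The design asks how the liver responds to furosemide-induced pre-renal azotemia and how far that response differs in mice without IL-6, a cytokine that drives acute phase protein synthesis in hepatocytes. Gene counts averaged 53940000 ± 11200000 (SD) per normal library, 59290000 ± 11500000 per WT vehicle library and 44650000 ± 9030000 per WT PRA library. They averaged 50320000 ± 6820000 per knockout vehicle and 52490000 ± 10500000 per knockout PRA library, with a range of 32073865 to 74041441 over the 19 libraries. The first principal component held 33.5% of the variance of log CPM and separated the PRA libraries, at 31.8 to 53.7, from all others, at -36.1 to -11.5. The labels do not say that replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

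The targeted gene, Il6 (ENSMUSG00000025746), was at 5 counts or fewer in every library except knockout PRA replicate 2. The normal libraries held 0, 2, 0 and 1 counts, the WT vehicle libraries 4, 0, 0 and 0, and the WT PRA libraries 2, 1, 0 and 3. Libraries labelled IL-6 knockout held 4, 1, 1 and 3 counts after vehicle and 3, 16 and 5 after PRA. The 16 counts in knockout PRA replicate 2 corresponded to 0.365 CPM of the library total without TMM scaling. These counts cannot check the genotype labels, because WT libraries were themselves at or near the floor and a whole-gene count can include transcript outside a deleted part. Below, "knockout" stands for libraries labelled IL-6 knockout. A neighbour of Il6, Abhd1 (ENSMUSG00000006638), an alpha/beta hydrolase family gene, divided the libraries as labelled. It was at 57.2 ± 7.21 and 59.4 ± 4.27 CPM in knockout vehicle and knockout PRA libraries and at 2.81 to 3.74 CPM on average in the WT groups. It was at 48.4 CPM in the lowest knockout and at 4.57 CPM in the highest WT library.

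In WT livers, PRA was accompanied by large rises of acute phase transcripts, which encode plasma proteins secreted by hepatocytes in systemic inflammation. Lcn2 (ENSMUSG00000026822), encoding the siderophore-binding protein lipocalin-2, rose 135-fold, from 6.51 ± 0.919 to 883 ± 135 CPM (SD, n = 4 each, log2 fold change 7.08 ± 0.40, SE, edgeR adjusted p = 7.08e-09). Serum amyloid A genes also rose. Saa2 (ENSMUSG00000057465) went from 34.4 ± 23.1 to 7096 ± 1762 CPM (206-fold, edgeR adjusted p = 8.32e-07) and Saa1 went from 120 ± 52.8 to 7615 ± 1501 CPM (63.6-fold, edgeR adjusted p = 1.18e-07), and without WT vehicle replicate 1 the log2 fold change of Saa2 was 8.28 in place of 7.68. Reads shared by these near-identical copies make their separate values uncertain. Serpina3n, a serine protease inhibitor, rose 8.66-fold to 5528 ± 1286 CPM, Orm2, an orosomucoid, 21.6-fold to 146 ± 41.3 CPM, and haptoglobin (Hp) 4.22-fold to 14680 ± 1898 CPM (edgeR adjusted p = 6.33e-13, 4.15e-09 and 6.41e-07). Of the 33 positive acute phase genes, 29 rose and 4 did not pass over all genes, and 31 rose adjusted over the list alone, with a median log2 fold change of 1.55 (camera adjusted p = 6.19e-66, and 2.46e-05 with an estimated correlation). Neutrophil markers rose in the same libraries (median 2.86), at far lower levels. Hamp, encoding the iron hormone hepcidin, did not pass (0.68 ± 0.24, edgeR adjusted p = 0.0533), but passed without WT vehicle replicate 2 (0.89, adjusted p = 0.0161). Agt, encoding angiotensinogen, rose 1.70-fold (edgeR adjusted p = 0.00022). In the list of the IL-6 receptor and STAT3 feedback, 12 of 22 genes rose over all genes and 12 adjusted over the list alone (median 0.68, camera adjusted p = 1.68e-13, and 0.000139 with an estimated correlation). Its transcription factors Cebpb and Cebpd rose 3.64-fold and 4.85-fold. Socs3, a feedback inhibitor of STAT3, rose 3.70-fold (edgeR adjusted p = 0.00324).

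**Figure D1:**
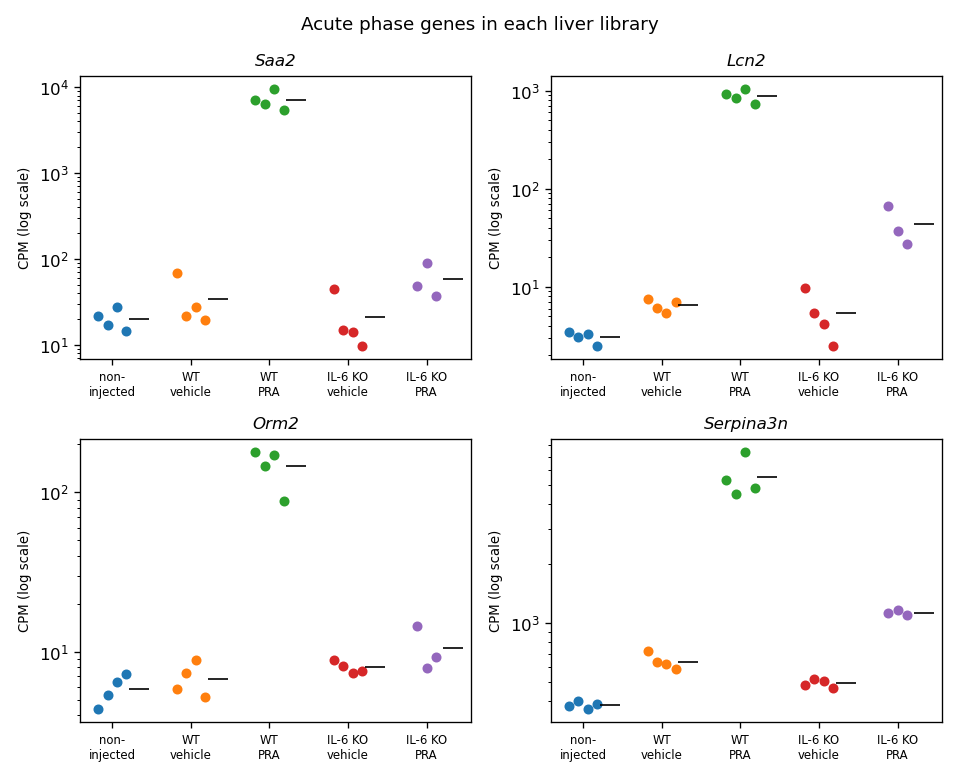
CPM of Saa2, Lcn2, Orm2 and Serpina3n in each of the 19 libraries on a log axis, by group, with a black dash at the group mean. The WT PRA means of 7096, 883, 146 and 5528 CPM lie above the knockout PRA means of 58.5, 43.8, 10.5 and 1127 CPM.

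Glucocorticoid-responsive and fasting genes rose in the same livers. Ddit4, an mTORC1 inhibitor induced by stress, rose 23.3-fold, from 9.04 ± 2.26 to 211 ± 32.2 CPM (n = 4 each, log2 fold change 4.54 ± 0.40, edgeR adjusted p = 1.05e-06). The metallothionein Mt2 rose 20.2-fold to 1942 ± 283 CPM (4.34 ± 0.44, edgeR adjusted p = 4.92e-06). Rasd1, a dexamethasone-induced Ras-related gene, rose 21.0-fold, to 11.7 ± 1.95 CPM. Of 22 glucocorticoid-responsive genes, 18 rose over all genes and 20 adjusted over the list alone (median 1.49, camera adjusted p = 1.16e-19, and 0.0134 with an estimated correlation). Of 19 gluconeogenesis and fasting genes, 9 rose over all genes and 11 adjusted over the list alone (median 0.61, camera adjusted p = 7.21e-06, and 0.0134 with an estimated correlation). Gadd45b rose 10-fold and Igfbp1, which encodes a binding protein of insulin-like growth factors, 19-fold to 936 ± 218 CPM. Amino acid catabolism genes rose in 14 of 34 cases over all genes and 19 adjusted over the list alone (median 0.31, camera adjusted p = 3.53e-08, and 0.149 with an estimated correlation). They were led by Aass, Sdsl, Kmo and tyrosine aminotransferase, Tat (4.46-fold, to 5942 ± 433 CPM). In the urea cycle and ammonia list 4 of 17 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 0.016, and 0.301 with an estimated correlation). Slc25a15, the mitochondrial ornithine carrier, rose 2.02-fold.

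Among named genes, the largest falls in WT PRA livers included genes of lipid and bile acid metabolism. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 22.0 ± 14.3 CPM against 118 ± 43.7 CPM after vehicle (log2 fold change -2.41 ± 0.43, edgeR adjusted p = 0.00101). G0s2, an inhibitor of triglyceride lipase, was at 21.1 ± 6.67 against 148 ± 59.0 CPM (-2.81 ± 0.48, edgeR adjusted p = 0.000666). Acot3, an acyl-CoA thioesterase (-7.05 ± 1.43, edgeR adjusted p = 0.00256), and the fatty acid hydroxylase Cyp4a14 (-3.62 ± 0.80, edgeR adjusted p = 0.00478) fell as well. Neither passed in limma-voom with sample weights (adjusted p = 0.073 and 0.0584). WT vehicle replicate 4 had 48.6 CPM of Acot3 against at most 5.77 CPM in the other WT vehicle libraries, and without it the values of Acot3, Cyp4a14 and Cyp4a10 were -5.02, -2.74 and -1.86. In WT PRA libraries Acot3 was at 0.102 ± 0.0841 CPM, near the limit of a count of 0, so the size of its fall is uncertain. Dclk3, Smad9, Cyp4a10 and Tlr12 fell by 2.90, 2.68, 2.48 and 2.44 on the log2 scale. The whole PPAR-alpha and fatty acid oxidation list did not pass, with 2 genes up and 7 down of 30 over all genes and 3 and 7 adjusted over the list alone (camera adjusted p = 0.138).

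Stress lists moved upward in WT PRA against vehicle, a comparison that does not show a rise over normal livers. Immediate early genes rose in 16 of 26 cases over all genes and 17 adjusted over the list alone (median 1.25, camera adjusted p = 1.76e-10, and 0.0539 with an estimated correlation), with Btg2 5.52-fold higher. The list of p53 targets and growth arrest had 10 genes up and 1 down of 21 over all genes, and 10 and 2 adjusted over the list alone (camera adjusted p = 1.1e-05, and 0.0282 with an estimated correlation). Its leading members, Btg2, Gadd45b and Trp53inp1, are also induced by other stresses. In the hypoxia list 9 of 24 rose by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.00773, and 0.0282 with an estimated correlation). Pfkfb3 and Aldoa, both of glycolysis, led it. Pfkfb3 was at 40.5 ± 5.84 CPM after PRA and 7.34 ± 3.39 CPM after vehicle. In normal livers it was at 35.0 ± 4.86 CPM, so its PRA level was close to the normal one. The ER stress list had 13 of 31 up over all genes and 15 up with 1 down adjusted over the list alone (camera adjusted p = 0.000467, and 0.301 with an estimated correlation). The heat shock list had 4 of 18 up in both counts, with Bag3 2.06-fold higher (camera adjusted p = 0.00302, and 0.537 with an estimated correlation). With the preset correlation, the ER stress and heat shock lists were also lower after vehicle than in normal livers, as given below. The NRF2 list had 5 of 24 up over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00886, and 0.301 with an estimated correlation). Hmox1, the heme-degrading oxygenase in that list, rose 9.98-fold, to 196 ± 86.0 CPM (edgeR adjusted p = 3.07e-06). Complement genes rose in 13 of 29 cases over all genes and 20 adjusted over the list alone (camera adjusted p = 3.84e-06, and 0.0912 with an estimated correlation). C4b, which has a near-identical copy, and Serping1 came first. The coagulation list had 12 up and 6 down of 31, and 13 and 6 adjusted over the list alone (camera adjusted p = 0.000185, and 0.103 with an estimated correlation). Thbd, an anticoagulant receptor, rose 7.05-fold, and the fibrinogen chains Fga, Fgg and Fgb, which are acute phase proteins, rose 2.58-, 2.64- and 2.47-fold. The iron handling list had 4 up and 3 down of 21, and 6 and 5 adjusted over the list alone (camera adjusted p = 0.016, and 0.193 with an estimated correlation). Its leading members were Lcn2 and Hmox1. The call was lost without the members it shares with the acute phase list, an alternative chosen after seeing the data (adjusted p = 0.316).

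Markers of non-parenchymal and blood cells moved with treatment in WT livers. Neutrophil markers rose at low levels, with S100a8 at 3.36 ± 0.37 against 0.242 ± 0.0576 CPM (13.5-fold, edgeR adjusted p = 8.59e-08) and Il1r2, a decoy receptor of interleukin-1, 21.5-fold higher. Of 9 markers 7 rose and G0s2, which hepatocytes also express, fell over all genes, and 8 rose adjusted over the list alone (median 2.86, camera adjusted p = 5.3e-09, and 0.0134 with an estimated correlation). Monocyte markers rose in 6 of 14 cases over all genes and 7 adjusted over the list alone (camera adjusted p = 0.00124, and 0.0282 with an estimated correlation). They were led by Hp, an acute phase gene of hepatocytes, and Itgam (2.34-fold). Sinusoidal endothelial markers fell in 9 of 17 cases with 1 up over all genes, and in 10 with 1 up adjusted over the list alone (median -0.37, camera adjusted p = 0.000385, and 0.372 with an estimated correlation). Kdr, a VEGF receptor, fell from 29.1 ± 7.01 to 10.1 ± 2.05 CPM (log2 fold change -1.53 ± 0.17, edgeR adjusted p = 1.9e-06). Stellate cell and fibroblast markers fell in 6 of 15 cases over all genes and 7 adjusted over the list alone (camera adjusted p = 0.0319, and 0.537 with an estimated correlation). Ngfr and Lrat came first, and the call was lost without WT vehicle replicate 3 (adjusted p = 0.072), WT PRA replicate 2 (0.0987) or WT PRA replicate 4 (0.142). B and plasma cell markers had 6 of 13 down and 1 up over all genes, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.0292, and 0.362 with an estimated correlation, 0.0923 without WT vehicle replicate 3, and 0.1 when only these 2 groups were fitted). Its leading members, Ighd and Cd79a, were under 1 CPM on average in both groups, and Cd79a (-2.29) was -3.52 without WT PRA replicate 4. Red blood cell markers had 4 of 7 up and 1 down over all genes, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.0392, and 0.349 with an estimated correlation). They lost the call without WT vehicle replicate 1 (0.079) or 2 (0.0579) and without WT PRA replicate 2 (0.0732) or 4 (0.0764), with the filter of 1 CPM in 3 libraries (0.0627) and when only these 2 groups were fitted (0.146). Reads of the globin copies can be shared.

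The other lists did not pass camera in WT PRA against vehicle, except the periportal hepatocyte list (camera adjusted p = 0.0392, and 0.537 with an estimated correlation), in which 2 of 17 genes, Sds and Pck1, rose over all genes and 1 adjusted over the list alone. It was lost without WT vehicle replicate 1 (0.0783) or 4 (0.237) and WT PRA replicate 2 (0.101), and with the filter of 1 CPM in 3 libraries (0.0664). The counts of genes up and down over all genes, the same when adjusted over the list alone, were 3 and 1 of 14 negative acute phase genes (camera adjusted p = 0.161), 5 and 5 of 23 NF-kB targets and chemokines (0.155), and 5 and 1 of 30 interferon response genes (0.0784). They were 2 and 5 of 24 lipogenesis genes (0.302), 3 and 2 of 26 drug-metabolising P450 genes and xenosensors (0.168), and 1 and 5 of 29 cell cycle genes (0.659), again in both counts. They were also 3 and 1 of 17 sex-biased genes (0.442), 2 and 1 of 10 cholangiocyte markers (0.62) and 1 and 1 of 9 adipose and mesothelial markers (0.809). Of 24 cholesterol synthesis genes 2 fell (camera adjusted p = 0.155), and of 14 Kupffer cell markers 1 fell (0.13), in both counts. Counts over all genes and adjusted over the list alone were 4 and 2, then 5 and 2, of 21 bile acid genes (0.571), and 2 and 2, then 3 and 3, of 19 clock genes (0.809). They were 5 and 4, then 6 and 4, of 22 secreted hormone and renin-angiotensin genes (0.325), and 2 and 3, then 3 and 3, of 18 pericentral genes (0.642). Median, mean and test differed in sign in the bile acid, clock, sex-biased and pericentral lists. The mitochondrially encoded list (15 genes, median 0.15, camera adjusted p = 0.14) and the T and NK cell list (14 markers, median -0.26, camera adjusted p = 0.839) did not pass either.

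In all, 3437 of 15570 genes passed in WT PRA against vehicle, 1516 higher and 1921 lower, of which 495 and 572 changed at least 2-fold. The share of higher genes was 44.1% with TMM and 34% with upper quartile scaling, which moved the median log2 fold change of all genes to -0.07. Requiring a change beyond 1.5-fold (glmTreat) left 625 genes.

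In knockout livers, PRA was followed by rises of glucocorticoid-responsive and fasting genes. Mt2 rose 24.4-fold, from 28.6 ± 17.1 (n = 4) to 700 ± 146 CPM (n = 3, log2 fold change 4.61 ± 0.46, edgeR adjusted p = 7.63e-06). Rasd1 rose 22.2-fold (edgeR adjusted p = 9.17e-10), Mt1 13.5-fold (edgeR adjusted p = 1.73e-05), Ddit4 12.1-fold (edgeR adjusted p = 1.82e-05) and Inhbb, an activin subunit, 11.8-fold (edgeR adjusted p = 9.56e-11). Fam107a, a stress-responsive actin-binding gene, had the largest log2 fold change among named genes, 5.06 ± 0.61 (40.03 ± 13.7 against 1.16 ± 1.23 CPM, edgeR adjusted p = 4.67e-05), which was 6.20 without knockout vehicle replicate 2. The cell cycle inhibitor Cdkn1a rose 15.9-fold (edgeR adjusted p = 0.0015), a call lost when only these 2 groups were fitted (adjusted p = 0.0537). Its log2 fold change of 3.99 was 4.91 without knockout vehicle replicate 1. Of 22 glucocorticoid-responsive genes 21 rose, over all genes and adjusted over the list alone (median 2.08, camera adjusted p = 1.78e-29, and 0.00225 with an estimated correlation). Gluconeogenesis and fasting genes rose in 13 of 19 cases over all genes, and adjusted over the list alone 13 rose and 1 fell (median 0.82, camera adjusted p = 2.95e-11, and 0.00189 with an estimated correlation), led by Foxo1, Gadd45b and Lpin1. Among named genes the largest fall was in Cyp7a1 (9.19 ± 4.29 against 76.9 ± 9.98 CPM, -3.06 ± 0.51, edgeR adjusted p = 0.000738), followed by Tlr12, Dclk3, Klhdc7a and Lhfpl2.

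Some acute phase genes also rose in knockout livers, and the difference from the WT response was tested as the interaction. Lcn2 rose 8.09-fold, from 5.41 ± 3.05 to 43.8 ± 20.9 CPM (log2 fold change 3.02 ± 0.35, edgeR adjusted p = 2.77e-05), and Serpina3n 2.28-fold, from 495 ± 23.3 to 1127 ± 32.3 CPM (1.19 ± 0.13, edgeR adjusted p = 2.17e-06). Lrg1 rose 1.71-fold and Agt 1.55-fold. Hp (0.81 ± 0.21, edgeR adjusted p = 0.013) was lost without knockout PRA replicate 1 (adjusted p = 0.162). Saa1 (1.32 ± 0.38, edgeR adjusted p = 0.0243) was lost without knockout vehicle replicate 2 (0.0609) or 3 (0.0589) or knockout PRA replicate 1 (0.123) or 2 (0.0527). Saa2 did not pass (1.49 ± 0.53, edgeR adjusted p = 0.0678) but did without knockout vehicle replicate 1 (2.19, adjusted p = 0.0065), and Fgb (0.20 ± 0.16, 0.44), Orm2 (0.41 ± 0.25, 0.3) and Socs3 (0.25 ± 0.43, 0.747) did not pass. Of the 33 acute phase genes 14 rose over all genes and 16 adjusted over the list alone (median 0.45, camera adjusted p = 1.53e-12, and 0.0129 with an estimated correlation). Of 22 IL-6 receptor and STAT3 feedback genes 10 rose and 1 fell over all genes, and 13 and 4 adjusted over the list alone (median 0.41, camera adjusted p = 5.64e-07, and 0.00305 with an estimated correlation).

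Among other lists in knockout PRA, the immediate early (18 of 26 up, 21 adjusted over the list alone), p53 (8 of 21 up, 8 up and 1 down adjusted over the list alone) and hypoxia lists (8 of 24 up, 12 adjusted over the list alone) passed. Their camera adjusted p values were 9.49e-18, 8.92e-09 and 0.000738. With an estimated correlation they were 0.0121, 0.00685 and 0.00789. Interferon response genes fell in 11 of 30 cases over all genes and 12 adjusted over the list alone (median -0.58, camera adjusted p = 2.41e-06, and 0.398 with an estimated correlation). The GTPases Iigp1, Gbp7 and Gbp3 came first. B and plasma cell markers had 8 of 13 down and 1 up over all genes, and 9 and 1 adjusted over the list alone (median -1.75, camera adjusted p = 6.28e-06, and 0.0537 with an estimated correlation). Igkc, an immunoglobulin light chain, was at 0.580 ± 0.301 against 1.77 ± 0.312 CPM. Amino acid catabolism genes rose in 14 of 34 cases over all genes and 17 adjusted over the list alone (camera adjusted p = 2.33e-10, and 0.104 with an estimated correlation). The P450, NRF2, ER stress, urea cycle, iron, periportal (upward), stellate and endothelial (downward) lists passed only with the preset correlation (adjusted p = 0.183 to 0.607 with an estimated correlation). Neutrophil (median 0.82, camera adjusted p = 0.0782) and monocyte markers (median -0.42, 0.0699) did not pass. In all 2544 genes passed, 1240 higher and 1304 lower (48.7% higher with TMM, 35.3% with upper quartile scaling), 1671 without knockout PRA replicate 2 and 417 beyond 1.5-fold in glmTreat.

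**Figure D2:**
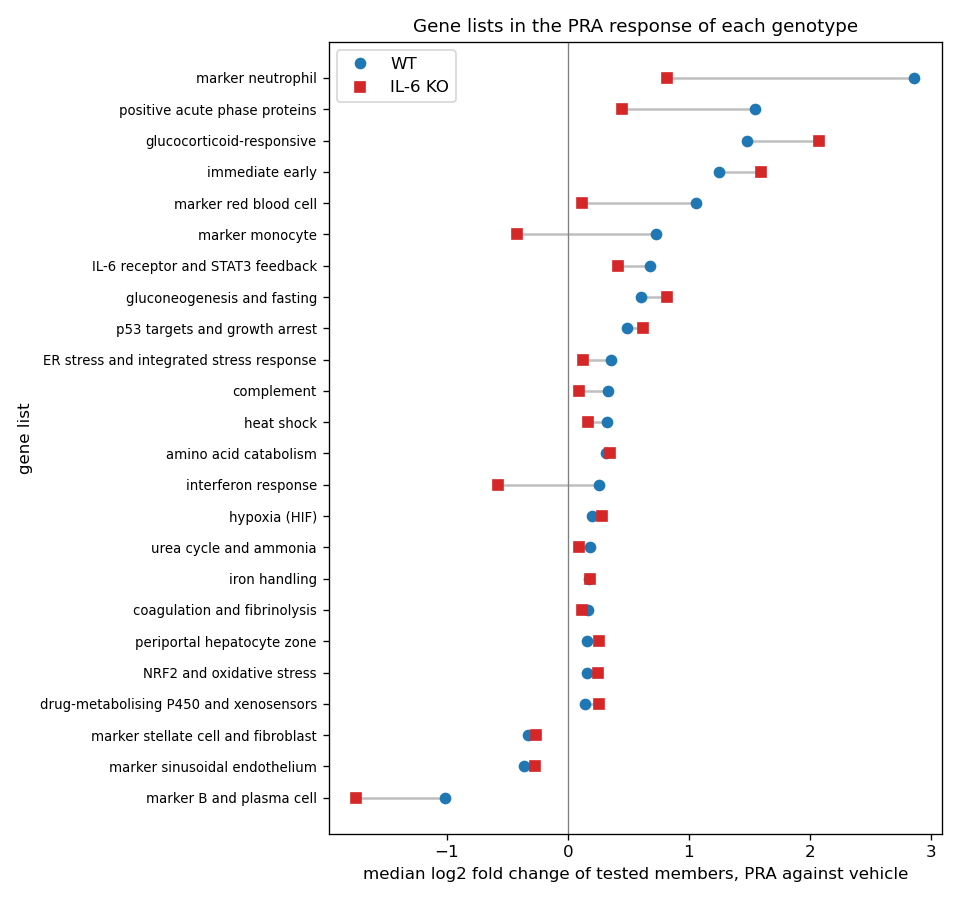
Median log2 fold change, PRA against vehicle, of the 24 gene lists that passed camera in either genotype, as circles for WT and squares for knockout. The acute phase medians were 1.55 in WT and 0.45 in knockout, and the glucocorticoid medians 1.49 and 2.08.

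The interaction tested whether the response to PRA differed by genotype, and acute phase genes were among those that differed. The interaction, as knockout response minus WT response on the log2 scale, was -6.19 ± 0.80 for Saa2 (edgeR adjusted p = 0.00115), -5.50 without knockout vehicle replicate 1 and -6.78 without WT vehicle replicate 1. It was -4.67 ± 0.55 for Saa1 (edgeR adjusted p = 0.000425), -4.06 ± 0.49 for Lcn2 (0.000434), -4.03 ± 0.36 for Orm2 (1.32e-05) and -1.93 ± 0.18 for Serpina3n (3.39e-06). Tifa, an adaptor of NF-kB signalling (-3.52 ± 0.34, edgeR adjusted p = 2.04e-05), and the synaptotagmin Syt12 (-3.07 ± 0.52, 0.00651) also differed. Of the 33 acute phase genes, 13 had a smaller response in knockout over all genes and 21 adjusted over the list alone (median -1.09, camera adjusted p = 9.09e-58, and 3.1e-05 with an estimated correlation). Hp (-1.27 ± 0.30, edgeR adjusted p = 0.0621) passed without knockout PRA replicate 1 (adjusted p = 0.000375), and Socs3 (-1.64 ± 0.58, 0.366), Hamp (-0.23 ± 0.36, 0.931) and Agt (-0.13 ± 0.19, 0.923) did not pass. Fgb, Fgg and Fga (-1.10, -1.09 and -1.05, edgeR adjusted p = 0.0247 each) lost the call without WT vehicle replicate 2 or 4, WT PRA replicate 3, knockout vehicle replicate 1 or 3 or knockout PRA replicate 2 or 3 (adjusted p up to 0.0878).

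Marker lists differed by genotype in the same direction. Neutrophil markers had an interaction median of -1.44 (1 of 9 lower over all genes, 6 adjusted over the list alone, camera adjusted p = 4.02e-10, and 0.0146 with an estimated correlation), with S100a8 at -2.74 ± 0.45 (edgeR adjusted p = 0.00328), and at -3.39 without knockout PRA replicate 1. Part of this interaction lay in the vehicle livers, where the markers were higher in knockout (median 0.75, S100a8 2.16), against a median of -0.69 under PRA (S100a8 -0.58, edgeR adjusted p = 0.356). Monocyte markers had a median of -1.20 (2 of 14 lower over all genes, 8 adjusted over the list alone, camera adjusted p = 1.06e-13, and 5.29e-05 with an estimated correlation), against 0.46 between genotypes under vehicle and -0.65 under PRA. The IL-6 receptor and STAT3 list had a median of -0.29 (1 of 22 lower in both counts, 0.00028, and 0.0253 with an estimated correlation). The interferon list (median -0.78, 1 of 30 lower over all genes, 13 adjusted over the list alone, camera adjusted p = 1.56e-20, and 0.0922 with an estimated correlation) was called with the preset correlation. The complement list was called likewise (-0.24, 6.06e-06, and 0.147 with an estimated correlation). The PPAR-alpha list was called in the same way (0.33, 0.185 to 0.378 without each library in turn, 1 of 30 higher over all genes, 3 adjusted over the list alone, 2.82e-06, and 0.384 with an estimated correlation). So were the NF-kB, coagulation, Kupffer, T and NK, B and plasma cell and red blood cell lists (lower) and the gluconeogenesis and immediate early lists (higher), none of which held with an estimated correlation (adjusted p = 0.311 to 0.79). The glucocorticoid list was not called (median 0.29, camera adjusted p = 0.101). In all 74 genes passed, 68 of them lower. This count was 40 without WT vehicle replicate 2, 42 without WT PRA replicate 3, 43 without knockout vehicle replicate 3, 37 without knockout PRA replicate 2, 178 in DESeq2 and 17 beyond 1.5-fold in glmTreat. Among named genes, the interaction was positive for Smad9 (1.74), Plin5 (1.24), Txnl4b (1.08), Ttl (1.02) and Zfp703 (0.75). Smad9 fell by 2.68 on the log2 scale in WT and by 0.94 in knockout, whereas Plin5, a lipid droplet protein, rose by 1.64 in knockout and did not pass in WT (0.41 ± 0.17, edgeR adjusted p = 0.1). These 5 genes each lost the call without WT PRA replicate 3, knockout vehicle replicate 3 or knockout PRA replicate 2, and without some other libraries (adjusted p up to 0.12).

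Compared directly under PRA, knockout livers had lower acute phase transcripts than WT livers. Saa2 was at 58.5 ± 28.4 (n = 3) against 7096 ± 1762 CPM (n = 4, log2 fold change -6.92 ± 0.72, edgeR adjusted p = 3.59e-05) and Lcn2 at 43.8 ± 20.9 against 883 ± 135 CPM (-4.33 ± 0.40, 6.07e-06). Serpina3n was at 1127 ± 32.3 against 5528 ± 1286 CPM (-2.29 ± 0.14, 9.88e-10) and Fgb at 7744 ± 859 against 17010 ± 2807 CPM (-1.14 ± 0.17, 0.000289). Of the 33 acute phase genes 22 were lower over all genes and 24 adjusted over the list alone (median -1.12, camera adjusted p = 1.34e-68, and 8.92e-06 with an estimated correlation). Among IL-6 receptor and STAT3 feedback genes 6 of 22 were lower over all genes, and 12 lower and 1 higher adjusted over the list alone (median -0.53, camera adjusted p = 1.37e-08, and 0.0015 with an estimated correlation). They were led by Ptpn2, a phosphatase acting on STAT proteins, Bcl3, and Nnmt, a nicotinamide methyltransferase. Saa1 (-5.03), Orm2 (-3.79) and AI506816 (-3.69) were lower too, and the citrate transporter Slc13a5 was at 0.431 ± 0.260 against 4.97 ± 1.69 CPM (-3.50 ± 0.38, edgeR adjusted p = 6.07e-06). Higher in knockout were Abhd1 (17.3-fold, edgeR adjusted p = 2.16e-13) and Cyp4a10 (6.35-fold, 232 ± 76.8 against 36.4 ± 8.78 CPM, 0.00556). Npas2 (8.79-fold, 0.0354) lost the call without any 1 of WT PRA replicates 2 to 4 or knockout PRA replicates 1 to 3 (adjusted p up to 0.107), and its log2 fold change of 3.14 was 3.75 without WT PRA replicate 1. Monocyte markers were lower (2 of 14 over all genes, 6 adjusted over the list alone, median -0.65, camera adjusted p = 0.000151, and 0.0127 with an estimated correlation). The interferon list was lower in 5 of 30 cases over all genes and 11 adjusted over the list alone (median -0.49, 1.15e-09, and 0.531 with an estimated correlation). Neutrophil markers had a median of -0.69 with 0 of 9 past the threshold in edgeR over all genes and adjusted over the list alone (camera adjusted p = 0.0219, and 0.615 with an estimated correlation), and 1, Retnlg, at an unadjusted edgeR p under 0.05 (0.0349). They lost the call without WT PRA replicate 1 (0.0505) or knockout PRA replicate 3 (0.309, median -0.41). Red blood cell markers were lower in 2 of 7 cases over all genes and 4 adjusted over the list alone (median -1.32, camera adjusted p = 0.0399, and 0.615 with an estimated correlation). They lost the call without WT PRA replicate 2 (0.0917) or 4 (0.0999) or knockout PRA replicate 3 (0.0935), and with the filter of 1 CPM in 3 libraries (0.0582). The complement, coagulation and heat shock lists (lower) and the PPAR-alpha list (higher) also passed only with the preset correlation (adjusted p = 0.531 to 0.985 with an estimated one). In all 591 genes passed, 256 higher and 335 lower in knockout, with 314 without knockout PRA replicate 1, 385 without WT PRA replicate 3, 927 in DESeq2 and 81 beyond 1.5-fold in glmTreat.

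Under vehicle the genotypes differed in 11 genes, several of them near Il6. Abhd1 was 15.3-fold higher in knockout (57.2 ± 7.21 against 3.74 ± 0.482 CPM, n = 4 each, log2 fold change 3.94 ± 0.15, edgeR adjusted p = 1.7e-13). AI506816 (ENSMUSG00000105987) was at 0.350 ± 0.104 against 4.80 ± 1.34 CPM (-3.78 ± 0.30, edgeR adjusted p = 3.58e-07). These 2 kept the call without any 1 library, though reads of overlapping or antisense genes cannot be told apart here. Galnt11, a glycosyltransferase gene (1.34-fold higher), Rint1 (-0.81 ± 0.14) and the zinc transporter Slc39a4 (31.6 ± 9.003 against 71.7 ± 3.84 CPM) passed at an edgeR adjusted p of 0.0155. The major urinary protein gene Mup21 (2.12-fold) and Susd4 (1.77-fold) passed at 0.0113, Ikbke (1.52-fold) at 0.0358 and the neutrophil marker S100a8 (4.47-fold, 1.11 ± 0.233 against 0.242 ± 0.0576 CPM) at 0.00913. Those 7 lost the call without WT vehicle replicate 4 (adjusted p = 0.0631 to 0.0686), and some also without another library. Galnt11 and Slc39a4 lost it without WT vehicle replicate 3 (both 0.0523), Slc39a4 and Mup21 without WT vehicle replicate 2 (0.0781 and 0.0684), and Rint1 without WT vehicle replicate 1 (0.05). Galnt11, Rint1 and Slc39a4 lost it without knockout vehicle replicate 3 (0.0835, 0.0835 and 0.1) and Galnt11 without knockout vehicle replicate 4 (0.0519). Ikbke lost it without any 1 of WT vehicle replicates 1 to 4 or knockout vehicle replicates 1 to 3 (up to 0.198). The count of genes was 2 without WT vehicle replicate 4, 6 without WT vehicle replicate 2, 5 without knockout vehicle replicate 3, 7 when only these 2 groups were fitted, 4 beyond 1.5-fold in glmTreat, 21 in limma-voom and 52 in DESeq2. Neutrophil markers (median 0.75, 1 of 9 higher over all genes, 3 adjusted over the list alone) and monocyte markers (median 0.46, 2 of 14 higher adjusted over the list alone) were higher in knockout. Their camera adjusted p values were 1.49e-08 and 5.41e-08 (0.036 and 0.00222 with an estimated correlation). The acute phase list had a median of -0.11 (5 of 33 lower adjusted over the list alone, camera adjusted p = 0.000988, and 0.41 with an estimated correlation, 0.102 without knockout vehicle replicate 4). Serpina3n was -0.37 ± 0.12 (edgeR adjusted p = 0.545). With the acute phase list, 14 lists in all were called with the preset correlation and not with an estimated one (adjusted p = 0.0883 to 0.533).

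**Figure D3:**
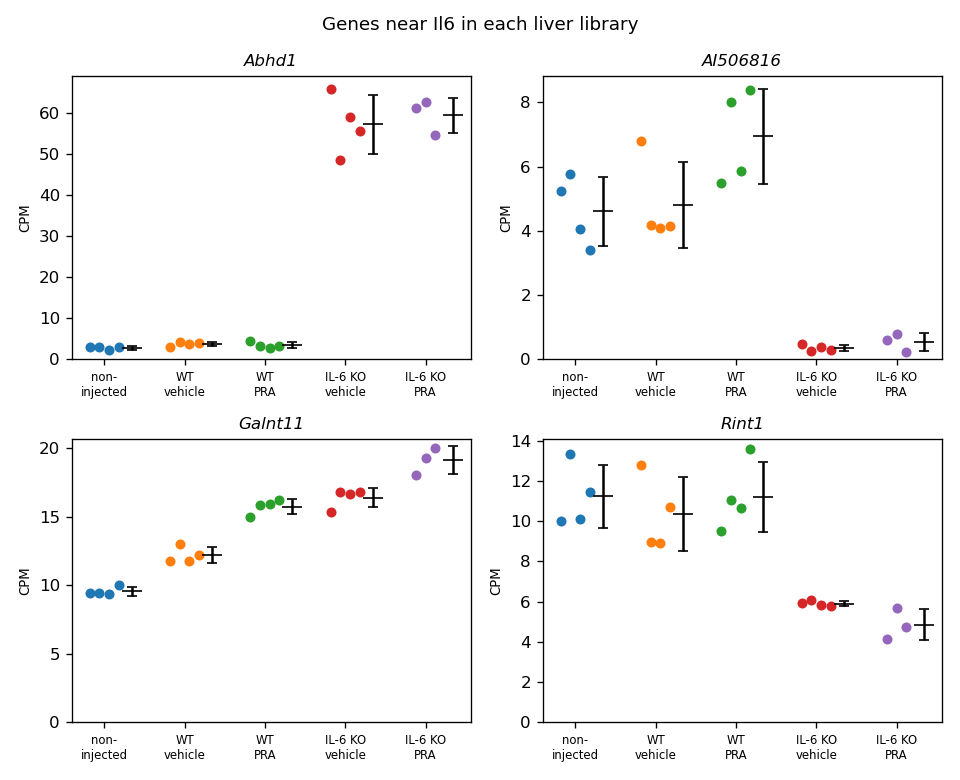
CPM of Abhd1, AI506816, Galnt11 and Rint1 in each library by group, with a dash at the group mean and a bar of 1 SD. Abhd1 separates the 7 knockout libraries, at 48.4 CPM or more, from the 12 WT libraries, at 4.57 CPM or less.

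Vehicle-injected WT livers differed from non-injected normal livers, with the largest rises among named genes in metallothioneins. Mt2 was at 96.3 ± 44.9 against 3.83 ± 0.372 CPM (25.0-fold, log2 fold change 4.65 ± 0.46, edgeR adjusted p = 8.68e-05) and Mt1 was 10.5-fold higher (edgeR adjusted p = 0.000416). Fkbp5, a glucocorticoid-induced co-chaperone, was 2.79-fold higher (141 ± 24.9 against 50.7 ± 7.17 CPM, edgeR adjusted p = 5.73e-05) and Serpina3n 1.66-fold (edgeR adjusted p = 0.0025). Of the 33 acute phase genes 7 were higher over all genes and 23 adjusted over the list alone (median 0.58, camera adjusted p = 5.33e-25, and 0.00334 with an estimated correlation). Lcn2 (1.08 ± 0.34, edgeR adjusted p = 0.115) and Saa1 (1.24 ± 0.36, 0.0881) did not pass. Glucocorticoid-responsive genes were higher in 5 of 22 cases over all genes, and 10 higher and 2 lower adjusted over the list alone (median 0.53, camera adjusted p = 8.53e-08, and 0.161 with an estimated correlation). Drug-metabolising P450 genes and xenosensors were higher in 3 of 26 over all genes and 9 adjusted over the list alone (median 0.39, 8.53e-08, and 0.167 with an estimated correlation), first Cyp3a13. Heat shock genes were lower in 4 of 18 cases over all genes and 6 adjusted over the list alone (median -0.32, camera adjusted p = 8.53e-08, and 0.311 with an estimated correlation). ER stress genes were lower in 3 of 31 over all genes, with 5 lower and 1 higher adjusted over the list alone (median -0.21, 0.00227, and 0.476 with an estimated correlation), led by the chaperone-related genes Dnajb9 and Manf. The ER stress median ranged over -0.251 to -0.063 without each library in turn. Of the lists called here, 20 did not hold with an estimated correlation (adjusted p = 0.131 to 0.624).

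Among single genes lower after vehicle, Pfkfb3, a regulator of glycolysis, was at 7.34 ± 3.39 against 35.0 ± 4.86 CPM in normal livers (-2.25 ± 0.33, edgeR adjusted p = 0.0025). Lars2, whose reads can be shared with mitochondrial rRNA, was at 90.9 ± 13.3 against 281 ± 56.2 CPM (-1.63 ± 0.20, 0.000357). Hspa1b (-2.95 ± 0.66, edgeR adjusted p = 0.033) was -1.51 without normal replicate 2, which had 86.2 CPM against at most 14.0 CPM in the other normal libraries. It lost the call without WT vehicle replicate 2, 3 or 4 (adjusted p up to 0.101). Bcl6 (-2.69 ± 0.48, edgeR adjusted p = 0.0104) and Noct (-2.17 ± 0.38, 0.00905) lost the call when only these 2 groups were fitted (adjusted p = 0.113 and 0.0932). In all 311 genes passed, 183 higher and 128 lower after vehicle. That count was 128 without normal replicate 2, 179 without WT vehicle replicate 2, 154 when only these 2 groups were fitted, 13 beyond 1.5-fold in glmTreat, 647 in DESeq2 and 648 in limma-voom.

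Against normal livers, WT PRA livers differed by both injection and PRA, a comparison that cannot separate them. Mt2 was 506-fold higher (log2 fold change 8.98 ± 0.55, edgeR adjusted p = 1.19e-08), Saa2 350-fold (8.45 ± 0.67, 2.48e-07), Lcn2 287-fold (8.16 ± 0.42, 1.35e-09) and Saa1 150-fold (7.23 ± 0.46, 1.32e-08, n = 4 each). Of the 33 acute phase genes 32 were higher over all genes and 32 adjusted over the list alone (median 1.96, camera adjusted p = 5.4e-84, and 5.08e-06 with an estimated correlation). Among named genes, the largest falls were in Acot3 (-5.34 ± 1.46, edgeR adjusted p = 0.013, 0.0929 in limma-voom with sample weights), Nrep, encoding the P311 peptide (1.87 ± 1.45 against 25.9 ± 14.2 CPM, 0.000254, log2 fold change -3.74, and -4.33 without WT PRA replicate 4), Dclk3 (-3.23 ± 0.28, 1.19e-07) and Cyp4a14 (-3.02 ± 0.79, 0.00989). The size of the fall of Acot3 is uncertain, as its WT PRA level was near the limit of a count of 0. In all 4421 genes passed, 2098 higher and 2323 lower, and 925 beyond 1.5-fold in glmTreat.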

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

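The tests of the acute phase difference and of the difference from non-injected livers were chosen after those results were seen. The splits of the libraries and the test of the Il6 neighbourhood were planned.

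The response to PRA differed between genotypes by the interaction test, with values as knockout response minus WT response on the log2 scale. The interaction was negative for Saa2 (-6.19), Saa1 (-4.67), Lcn2 (-4.06), Orm2 (-4.03), Tifa (-3.52), Syt12 (-3.07), S100a8 (-2.74), Ms4a4c (-2.61) and Serpina3n (-1.93). It was also negative for Orm1 (-1.29), Itih4 (-1.18), Fgb (-1.10), Lrg1 (-1.09), Fgg (-1.09), Fga (-1.05), Irgm1 (-0.88) and Ptpn2 (-0.72). Of these, Ms4a4c and Irgm1 fell in knockout (-2.30 and -0.56) and did not pass in WT (0.31 and 0.32), and the others rose in WT. Among named genes, the interaction was positive for Smad9 (1.74), Plin5 (1.24), Txnl4b (1.08), Ttl (1.02) and Zfp703 (0.75). Smad9 and Txnl4b fell less in knockout than in WT, and Ttl fell in WT and did not pass in knockout. Plin5 and Zfp703 rose in knockout and did not pass in WT. Without single libraries, Saa2 was -5.50 (knockout vehicle replicate 1) and -6.78 (WT vehicle replicate 1), and S100a8 was -3.39 (knockout PRA replicate 1). Ms4a4c, Fgb, Lrg1, Fgg, Fga, Irgm1, Ptpn2 and the 5 named genes with positive values lost the call without knockout vehicle replicate 3, and without some other libraries (edgeR adjusted p up to 0.125). Of the lists, the acute phase (median -1.09), neutrophil (-1.44), monocyte (-1.20) and IL-6 receptor and STAT3 (-0.29) lists differed.

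Technical explanations were weighed for the smaller acute phase response of knockout livers. Fewer neutrophils as the source could not be decided by a comparison of summed levels. The 13 acute phase genes called in the interaction summed to 84620 CPM in WT PRA and 29600 CPM in knockout PRA. They differed by 55020 ± 6520 CPM (SE). The 8 neutrophil markers summed to 13.35 and 9.195 CPM and differed by 4.16 ± 2.76 CPM, a ratio of 7.55e-05. The rule for this explanation asked for a marker difference as large as the acute phase one. Markers at such levels could not reach it even if lost entirely. Scaling was argued against, since the interaction median of the list was -1.09 or farther from 0 with TMM, RLE and upper quartile factors (highest camera adjusted p = 1.42e-56). A weaker response was not seen in the glucocorticoid list. Its median response in knockout over that in WT was 1.40 (95% bootstrap interval over members 0.962 to 2.15, 10000 draws), against 0.29 for the acute phase list. That interval resamples genes and not libraries, so it holds no spread between livers. The glucocorticoid list shares Mt1 and Mt2 with the acute phase list and covers only a part of the response, so a weaker response as a whole was not decided. Dependence of the acute phase response on IL-6 is a hypothesis that these tests leave open, along with any other difference between the lines, such as the variants considered next.

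The genes that differed between genotypes under vehicle lay near Il6 more often than other genes. Within 20 Mb of Il6, 5 of 218 tested genes passed (Abhd1, AI506816, Galnt11, Gm2420 and Rint1), against 6 of 15326 elsewhere (odds ratio 59.8, 95% interval 14.3 to 237, Fisher's exact test, 2-sided, p = 2.24e-07). This is consistent with variants of another strain carried beside the targeted locus, although an effect of the deletion on its neighbours was not tested separately. Under PRA the same window had an odds ratio of 2.04 (95% interval 1.14 to 3.42, exact p = 0.011) between genotypes, but at 40 Mb it was 1.45 (0.826 to 2.38, exact p = 0.138) and the call was lost. The 5 genes called near Il6 under vehicle were called between genotypes under PRA as well, at 10, 20 and 40 Mb. Called genes went from 16 of 218 tested at 20 Mb to 17 of 318 at 40 Mb, so the wider window mostly added genes that were not called. The lost call at 40 Mb therefore does not argue against a part played by variants near Il6, which was not tested. For the interaction, 1 of the 218 genes within 20 Mb passed (odds ratio 0.963, 95% interval 0.0239 to 5.59, exact p = 1), an interval too wide to decide.

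Vehicle-injected livers differed from non-injected livers in ways that the design cannot assign to injection alone. Mitochondrial rRNA summed to at least 1984 CPM in the normal libraries and at most 1452 CPM in the other 15 libraries. Among those 15, the WT vehicle libraries had at most 1365 CPM. Within groups, libraries with more of it had a lower score over 308 called genes (19 libraries, Pearson r = -0.507, permutation p = 0.0432, Spearman rho = -0.509, permutation p = 0.0747, r = -0.649 without the 2 libraries farthest from the median). A difference in RNA or library preparation may contribute. Collection at another time of day cannot be told apart from injection, because 3 clock genes passed adjusted over the list alone, too few to decide, and the labels give no hour. Reads shared with mitochondrial rRNA were argued against as the whole cause of the Lars2 difference, since the lowest normal ratio of Lars2 to mt-Rnr2 was 1.32 times the highest WT vehicle ratio (0.226 ± 0.0202 against 0.146 ± 0.0164, n = 4 each).

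A single library lay far from the others of its group in 14 of 216 groups of values examined, where chance gives about 10.8. Knockout PRA, with 3 libraries, was too small for this test and was not examined. In that group Hp ranged from 5596 to 12090 CPM and Saa3 from 3.72 to 25.7 CPM. Normal replicate 2 had 16.17% of reads not uniquely placed (others 14.07% to 14.42%), 68.61% of reads in genes (others 70.35% to 70.67%) and 86.2 CPM of Hspa1b (others 9.17 to 14.0). WT vehicle replicate 4 had 71.71% of reads in genes (others 68.99% to 69.43%) and 48.6 CPM of Acot3 (others 1.06 to 5.77). WT vehicle replicate 1 had 6.81 CPM of AI506816 (others 4.08 to 4.17) and 39.6 CPM of Kdr (others 25.0 to 25.9). Over all genes its limma-voom sample weight was 0.248, the lowest of the 19 libraries, with 0.511 for the next, knockout PRA replicate 3. Knockout vehicle replicate 1 had 44.7 CPM of Saa2 (others 9.57 to 14.98) and 15.3 CPM of Galnt11 (others 16.7 to 16.8), replicate 2 had 2.99 CPM of Fam107a (others 0.370 to 0.777) and replicate 3 had 36.2 CPM of Hmox1 (others 18.2 to 21.0). Normal replicate 1 had 23.4 CPM of Socs3 (others 6.10 to 8.35), replicate 3 had 0.883 CPM of Fam107a (others 0.126 to 0.189) and replicate 4 had 10.1 CPM of Galnt11 (others 9.35 to 9.45).

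Other splits of the same libraries were fitted to ask whether chance can be excluded for each count of genes. Of 35 splits, only the real one (1) gave as many genes in WT PRA against vehicle (3437, highest other 3), knockout PRA against vehicle (2544, highest other 1118) and knockout PRA against WT PRA (591, highest other 13). The same held for knockout vehicle against WT vehicle (11, highest other 5), WT vehicle against normal (311, highest other 7) and WT PRA against normal (4421, highest other 0). A share of 1 in 35, the smallest these splits can give, is under 0.05 for each comparison taken alone. It was not corrected over the comparisons. Mixed splits also put a real difference into the spread within groups, so the gap to the highest other count adds no support. The split with 1118 genes kept all 3 knockout PRA libraries together with knockout vehicle replicate 2. For the interaction 2 of 100 splits gave at least the real 74 genes, the other one 303. That split exchanged labels among vehicle libraries alone, as did one that gave 65 genes. A count that high points to a structure of the samples. With all PRA labels true, both still held the difference between genotypes under PRA, and no other source was tested. Splits that also exchanged PRA libraries put that difference into the spread within groups and gave 0 to 3. The splits therefore do not decide whether chance accounts for the interaction count.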

How the results depend on the processing

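The lists without acute phase members, the acute phase list without Mt1 and Mt2, the neutrophil list without G0s2 and the lists under upper quartile scaling were chosen after seeing the data. The other alternatives were planned. The counts of genes past the threshold stayed within 1.5 times under RLE, upper quartile scaling and both filters. Against a fold of 1.5 (glmTreat) they were 625 and 417 for PRA in WT and knockout, 17 for the interaction, 81 for knockout against WT under PRA, 4 under vehicle, 13 for vehicle against normal and 925 for WT PRA against normal, as a stricter hypothesis requires fewer. DESeq2 gave 178 (74 shared with edgeR) for the interaction, 927 (585 shared) between genotypes under PRA, 52 (11 shared) under vehicle and 647 (311 shared) for vehicle against normal. Limma-voom gave 21 (10 shared) and 648 (295 shared) for the last pair of comparisons, and fitting only the groups compared gave 7 (5 shared) and 154 (127 shared). In the simulated counts, unchanged genes made up 16.7%, 16.1% and 14.5% of DESeq2 calls for the interaction, genotypes under vehicle and vehicle against normal. They made up 7.06%, 4.29% and 5.56% of edgeR calls. For limma-voom the shares were 4.65%, 5.07% and 6.38%. Those counts were drawn with the spread that edgeR estimated, and the cause of the differences in the data was not tested.

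Without each library in turn, the counts ranged over 2754 to 3414 (WT PRA), 1671 to 2499 (knockout PRA), 37 to 95 (interaction), 314 to 489 (genotypes under PRA), 2 to 15 (genotypes under vehicle), 128 to 299 (vehicle against normal) and 3629 to 3928 (WT PRA against normal). The acute phase median ranged over 1.45 to 1.55 in WT, 0.34 to 0.51 in knockout and -1.19 to -0.95 for the interaction. No named gene changed sign where it passed the threshold with or without a library. Of those that passed in neither fit, Saa3 (0.48, and -1.0 without knockout PRA replicate 1) and Hamp (0.45, and -0.045 without knockout PRA replicate 2) changed sign for PRA in knockout. Agt did so between genotypes under PRA and vehicle, and Fgb under vehicle. Among named genes, 298 of the left-out values lost the threshold, 7 gained it and 3047 stayed on the same side of it. Apart from the fixed set, genes were named because they passed in the main fit, so more losses than gains follow from that choice. Named genes lost it in 35 cases when only the groups compared were fitted, 23 without the low-count filter, 14 with the replicate block, 14 in limma-voom, 3 under upper quartile scaling and 1 with the filter of 1 CPM in 3 libraries. They gained it in 4, 0, 4, 2, 0 and 1 cases in that order and in 5 in DESeq2. List calls were lost in 11 cases with that filter, 4 when only the groups compared were fitted and 1 under upper quartile scaling. Only lists called in the main fit were rerun, so calls could only be lost. For WT PRA against normal, only the acute phase list was rerun. The cell cycle list under vehicle changed sign without WT vehicle replicate 1 (0.02, camera adjusted p = 0.696, lowest left-out median -0.536), and 94 other left-out list values lost the call. Among these, the medians of the Kupffer list (-0.011 without WT vehicle replicate 4, adjusted p = 0.71) and the acute phase list (0.003 without knockout vehicle replicate 4, 0.102) under vehicle changed sign, though the direction in camera did not.

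With an estimated correlation 77 list calls were lost and 26 kept, and fry lost 46. Without members shared with the acute phase list 5 calls were lost: iron handling in WT (0.07, adjusted p = 0.316) and knockout (0.07, 0.0782), and coagulation for the interaction (-0.03, 0.258), under PRA between genotypes (-0.003, 0.705) and for vehicle against normal (0.10, 0.0593). The Il6 window gave odds ratios of 59.5, 70.9 and 40.5 under vehicle at 5, 10 and 40 Mb. Under PRA they were 2.53, 2.27 and 1.45, the last without a call (exact p = 0.138), and no window passed for the interaction (exact p = 0.193 to 1).

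Replicate numbers are shared between groups, and the deviations of same-numbered libraries gave no clear sign that the numbers pair the libraries. These deviations correlated over 0.1 in 1 of 4 pairs for PRA in WT (-0.0804 to 0.115) and 1 of 3 in knockout (-0.12 to 0.193). For WT vehicle against normal the correlations were -0.219 to -0.0553. With 3 or 4 libraries per group these values cannot exclude a pairing. With the number as a block, the counts were 3204, 2175, 74 (62 shared), 496, 11 (8 shared), 291 and 4205, in the order above, and the acute phase medians 1.53, 0.34 and -1.10. Of the 5 comparisons simulated, the interaction had the least power at this depth: 4.48% of simulated 1.5-fold changes were recovered there, against 43.3% for PRA in WT. The simulations changed far fewer genes than the 3437 called for PRA in WT, and recovery at an adjusted threshold depends on that number.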

Other observations

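The comparison of the 2 genotypes' responses was made after both were seen.

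The responses to PRA of WT and knockout livers, which share no libraries, overlapped widely. Of 15570 tested genes, 765 were called higher in both genotypes, where independent lists would share 121, and 829 were called lower in both, where independent lists would share 161. The calls came from the same fit with a shared spread per gene, and genes with more power pass more readily in both. They are therefore not independent, and the excess over these numbers is not a test of a shared response. In the opposite direction, 8 genes called higher in WT were called lower in knockout. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.652 and a Spearman correlation of 0.628. The sign was the same in knockout for 3226 of the 3437 genes called in WT.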
